A study of Mus musculus with 6 samples.

How the data were processed

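Gene expression was measured on 6 Affymetrix mouse genome arrays, each hybridised with 1 pool of RNA. The pools came from the testis at embryonic day 13.5 (E13.5), the testis at postnatal day 1 (PN1) and whole male embryos at E13.5, each from the 129/Sv strain and from the consomic strain 129.MOLF-Chr19, in which chromosome 19 comes from the MOLF strain. The E13.5 testis pools held 20 testis pairs per strain, the PN1 pools held 12 pairs for 129/Sv and 25 pairs for 129.MOLF-Chr19, and the embryo pools held 3 embryos per strain. Each of the 6 groups therefore had 1 array.

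The deposited values are probe set signals in intensity on a linear scale, summarised by the authors by a method that the deposited record does not state. The table held 45101 probe sets, 64 of them controls. Of these, 34958 were listed with exactly 1 gene symbol, 932 with several symbols and 9211 with none. Each value was raised to the 25th percentile of its array where it lay below it, log2 transformed and centred on the median of the non-control probe sets of that array. A gene was represented by its single-symbol probe set with the highest mean log2 value over the 6 arrays of both strains, which gave 18193 genes, 9010 of them with several probe sets. Chromosomes were taken from the RefSeq annotation of assembly GRCm38.p6, which placed 609 measured genes on chromosome 19. Array medians ran from 220.5 to 250.7 and maxima from 18300 to 23930. The number of arrays limits the precision.

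In each tissue the strain difference was the log2 value in 129.MOLF-Chr19 minus that in 129/Sv, for genes whose higher array lay above its own median. With 1 array per group no test was possible within a tissue, and genes were counted at a difference of 2-fold or more. The fold at which a value at the floor is compared is a lower bound. 4 comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, Benjamini-Hochberg adjustment at 0.05). These were the strain difference across 3 tissues with tissue as a block, the strain difference across the testis at 2 ages with age as a block, PN1 testis against E13.5 testis, and E13.5 testis against E13.5 embryo, the last pair fitted over all 6 arrays with strain as a block. Genes entered a fit when they lay above the array median in at least 2 arrays. The spread in these fits came from the interaction of strain and tissue, with 2 residual degrees of freedom over 6 arrays and 1 over the 4 testis arrays. All p-values are two-sided.

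25 gene lists with 310 genes, 280 of them measured, were fixed before the data were examined, as were the comparisons, the thresholds, the rule for naming genes and the alternatives, except those named as added. In each tissue, a list's median strain difference was placed as a percentile among 10000 random lists matched on mean expression, without a p-value. In the limma fits the lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Members past 0.05 were counted over all genes and after adjustment over the list alone. The genes named per tissue were the 10 with the largest rise and the 10 with the largest fall past 2-fold, chromosome 19 genes changed with one sign in several tissues, list members past 2-fold, and Sf1, Pum3 and Cox15, which the submitters name. In the fits, the 10 rising and 10 falling genes of smallest p were named, with up to 4 members of each list, and where none passed the 5 of smallest p. Genes outside this rule are marked as chosen after their values were seen. 

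The alternatives were the values as deposited, quantile normalization, lowess, no floor, a floor at the 40th percentile, no expression filter, a filter at the 75th percentile, the mean of all probe sets of a gene, each probe set on its own, 1.5-fold and 3-fold thresholds, limma without trend or with robust estimation, fits without the block, leaving out each array or pair, and camera with an estimated correlation. In the fits by age and by tissue, only arrays of the 2 compared groups were left out in turn. The fits were tested on simulated data with 200 changed genes each. They called 82 to 100% of genes changed by 1 on the log2 scale and 99 to 100% of those changed by 2, with 10 or 11 false calls. The simulated noise was normal, independent between genes and drawn from the variances that each fit had estimated. These rates therefore check the fits under their own assumptions and need not hold for the real arrays, where fewer genes may differ. Probe sets with several gene symbols or none were left out of the gene comparisons. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.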

Results

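Transcript levels were compared between 129/Sv mice and the consomic strain 129.MOLF-Chr19 in the E13.5 testis, the PN1 testis and the whole male E13.5 embryo, with 1 array of pooled RNA for each of the 6 groups. The strain comparison asks which genes differ in the testis at the ages when testicular germ cell tumors arise in 129.MOLF-Chr19, and the embryo asks whether a difference is specific to the gonad. The 2 strains of a tissue were the most alike: Pearson's r across genes was 0.974 in the E13.5 testis, 0.967 in the embryo and 0.964 in the PN1 testis. The testes of both ages joined each other at a distance (1 minus r) of 0.0925 before the embryos joined at 0.144, and the lowest r between any 2 arrays was 0.823. Genes are not independent replicates for these correlations. The Gapdh control ratio of 3 prime to 5 prime signal ran from 0.895 to 0.966 over the 6 arrays. The Actb ratio was 1.84 on the PN1 array of 129.MOLF-Chr19 and 1.09 to 1.19 on the other 5.

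In the E13.5 testis, 7 genes were at least 2-fold higher and 4 at least 2-fold lower in 129.MOLF-Chr19 among 12526 compared. Chgb, which encodes the secretory granule protein chromogranin B, was highest, with a log2 difference of 1.71 (intensity 258 in 129/Sv and 778 in 129.MOLF-Chr19). It was followed by Tmem258, a subunit of the oligosaccharyltransferase complex, at 1.52, Nenf at 1.17, the lysine acetyltransferase gene Kat2b at 1.13, Rex1bd, which was 2.14-fold higher, Arpc4 at 1.02 and the cathepsin gene Ctsz at 1.02. The other expressed probe sets of the higher genes, 5 in 4 genes, had a median of 0.62, those of Ctsz 0.62 and 0.96, and none passed 2-fold. Lipo3 was lowest at −1.33, with 129.MOLF-Chr19 at the floor, so that it was at least 2.51-fold lower. Usp50 at −1.14, the ubiquitin ligase gene Trim8 at −1.03 and Gm15708 at −1.01 followed. No array was repeated, so no strain difference within a tissue has a replicate check. Before centring, the array medians differed by −0.117 (log2, 129.MOLF-Chr19 minus 129/Sv), and the values here are relative to that shift. On the values as deposited 4 genes were higher and 6 lower, with quantile normalization 3 and 3, and with the mean of all probe sets of a gene 3 and 2.

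Among the fixed gene lists in the E13.5 testis, cell cycle genes lay toward 129.MOLF-Chr19. Their median log2 difference was 0.26, the 99.0 percentile of random lists, and 13 of 15 members were positive. The erythroid list had a median of 0.41 (99.6 percentile, 5 of 5 positive) and the endothelial list 0.27 (97.8 percentile, 8 of 11 positive). The mesonephros and kidney list had a median of −0.20 (1.42 percentile) and the peritubular and interstitial list −0.07 (1.90 percentile, 2 of 12 positive). No member of any fixed list passed 2-fold in this tissue. Because the random lists lack the correlation between list members, an extreme percentile is by itself no evidence of a strain effect, here or in the other tissues. The list of Sf1, Pum3 and Cox15 lay at the 2.41 percentile, and the other 19 lists lay between the 3.89 and 92.1 percentiles. With the mean of all probe sets of a gene, the cell cycle list lay at the 88.8 percentile, the endothelial list at the 91.9 and the mesonephros list at the 3.11. Under that setting the germ cell list went from the 17.1 to the 1.21 percentile, the muscle list from 79.0 to 99.7, the immediate early and heat shock list from 92.1 to 98.2 and the list of Sf1, Pum3 and Cox15 to 0.01.

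The PN1 testis showed the largest number of strain differences, 26 genes at least 2-fold higher and 113 at least 2-fold lower in 129.MOLF-Chr19 among 12729 compared. The highest was Cer1, a secreted antagonist of Nodal and BMP signals, at the floor in 129/Sv (intensity 89.4) and at 1076 in 129.MOLF-Chr19, a log2 difference of 3.19 or at least 9.16-fold. Trh, the thyrotropin-releasing hormone precursor, was 3.06 higher (157 and 1310). Spink1 at 2.12 and the homeobox gene Otx2 at 1.77 were also at the floor in 129/Sv, so their folds are lower bounds. The glucose transporter gene Slc2a3 was 1.95 higher, Cd24a 1.80, Amot 1.78, the phosphatase gene Mtm1 1.72, the tight junction gene Cldn6 1.60 and Car2 1.39. Pou5f1, the pluripotency factor also called Oct4, was 1.36 higher (177 and 454). The epithelial genes Cdh1 at 1.27, Krt8 at 1.15 and Krt18 at 1.14 and the DNA methyltransferase gene Dnmt3b at 1.18 also passed 2-fold. These last 4 were chosen after their values were seen.

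The other expressed probe sets of the higher PN1 genes mostly moved with the probe set that represented the gene. Of 15 such probe sets in 11 genes, 14 had the same sign and 9 passed 2-fold, with a median log2 difference of 1.11. The second probe sets of Cer1 (1.58), Slc2a3 (1.90) and Mtm1 (1.98) and those of Cd24a (1.81 and 1.32) were all higher, whereas those of Amot were at 0.27 and −0.07. With the mean of all probe sets of a gene, 17 genes were at least 2-fold higher and 40 lower. In the E13.5 testis, where Cer1 was at the floor in both strains, the 26 genes had a median strain difference of 0.22, against 0.06 for all genes, and in the embryo it was 0.04.

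**Figure D1:**
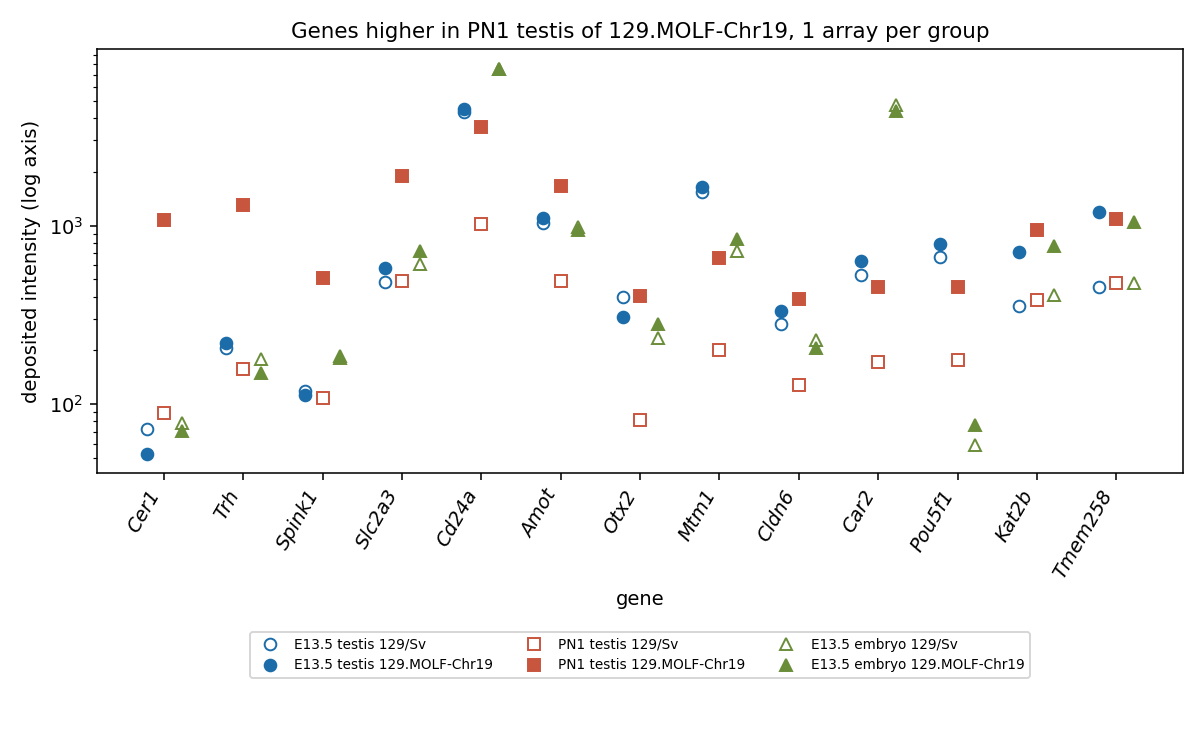
Deposited intensity (log axis) of the named genes at least 2-fold higher in the PN1 testis of 129.MOLF-Chr19, with 1 point per array. Cer1 is at 89.4 in the PN1 testis of 129/Sv and 1076 in that of 129.MOLF-Chr19, Trh at 157 and 1310.

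The lower PN1 genes were led by the splicing factor gene Mbnl2 at −3.15, the long noncoding RNA Tug1 at −3.01, the kinesin gene Kif5b at −2.80 and the histone demethylase gene Kdm6b at −2.65. The interstitial transcription factor gene Nr2f2 was at −2.58, the syndecan gene Sdc4 at −2.42, Plpp3 at −2.25, Gas7 at −2.18, Sgpl1 at −2.17 with 129.MOLF-Chr19 at the floor, and Gpm6b at −2.16. Members of the fixed lists among the lower genes were also the germ cell RNA-binding protein gene Dazl at −1.97, Maf at −1.04, Acta1 at −1.15 and Junb at −1.01, the last at the floor in 129.MOLF-Chr19. The other expressed probe sets of these genes largely did not follow: 177 probe sets in 85 of the 113 genes had a median log2 difference of −0.04 (interquartile range −0.41 to 0.18), and 24 passed 2-fold in the same direction. Those of Tug1 were at 0.02 and 0.36, those of Kdm6b at 0.03 and 0.27, that of Dazl at 0.46 and those of Nr2f2 at −0.15, −0.18 and 0.00. Sdc4 had a second probe set at −1.01, and Mbnl2 had one at −2.65 and 3 between −0.07 and 0.27. Of 4988 genes with several expressed probe sets, 6 had all of them at least 2-fold higher (Cd24a, Cer1, Emb, Krt8, Mtm1 and Slc2a3) and 2 had all of them at least 2-fold lower (Rian and Sdc4), Emb and Rian chosen after their values were seen. The Actb control probe sets were also lower: on the 129.MOLF-Chr19 array the 3 prime signal was 5118 against 15200 in 129/Sv, the middle signal 1517 against 12440, and the 5 prime signal 2778 against 12810. Actb is itself 1 of the 113 lower genes, at −2.10, a value chosen after it was seen, so its control probe sets are no separate control. Control probe sets were not counted among the other expressed probe sets, where that of Actb was at −0.33.

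**Figure D2:**
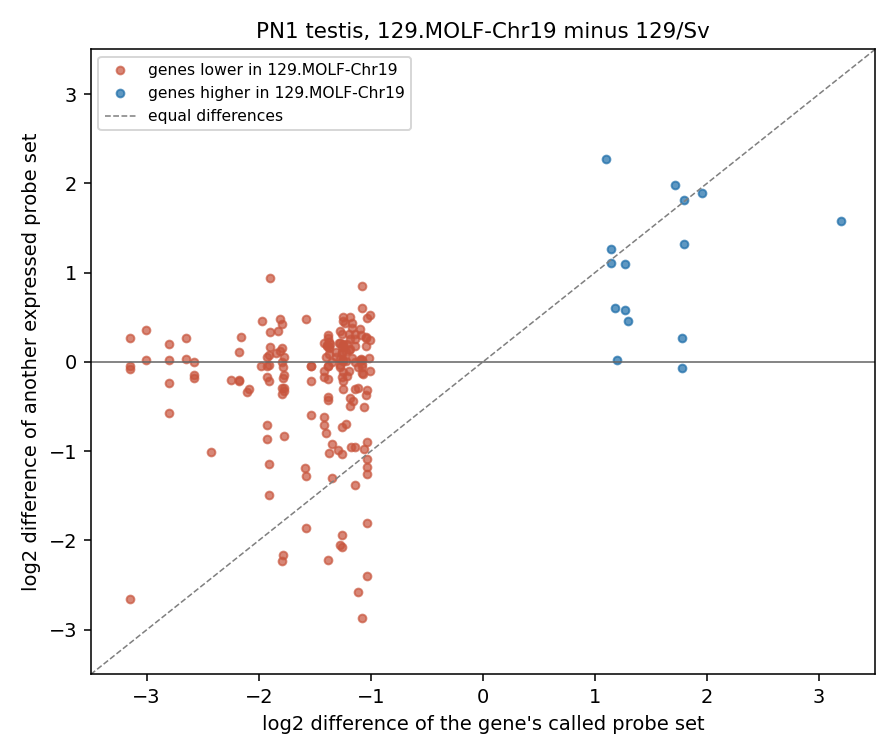
Log2 strain difference in the PN1 testis of the probe set representing each changed gene (horizontal axis) and of each other expressed probe set of that gene (vertical axis). The 15 other probe sets of the higher genes have a median of 1.11 and the 177 of the lower genes a median of −0.04.

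By cell type in the PN1 testis, the peritubular and interstitial list lay lowest, with a median of −0.34 (0.025 percentile) and 2 of 11 members positive. With the mean of all probe sets its median was −0.25, at the 0.05 percentile. The skeletal and cardiac muscle list lay at −0.17 (2.16 percentile). The cell cycle list was at 0.17 (99.5 percentile, 13 of 15 positive), the cytochrome c oxidase list at 0.13 (99.4 percentile, 12 of 14 positive) and the interferon response list of 3 compared genes at 0.47 (99.8 percentile). With the mean of all probe sets the cell cycle list stayed at 99.5, cytochrome c oxidase lay at 90.9 (median 0.08), interferon response at 93.1 (median 0.21) and muscle at 3.20, and the Leydig cell list went from 73.7 to 97.6 (median 0.15). The germ cell list, with 20 genes compared, had a median of 0.00 (26.4 percentile), and Dazl was its 1 member past 2-fold. The pluripotency and embryonal carcinoma list had a median of −0.01 (26.5 percentile) with Pou5f1 as its 1 member past 2-fold, and with the mean of all probe sets it had a median of 0.14 at the 97.1 percentile. The list of Sf1, Pum3 and Cox15 lay at the 1.33 percentile, and the other lists lay between the 7.04 and 94.9 percentiles.

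In the E13.5 embryo, 7 genes were at least 2-fold higher and 36 at least 2-fold lower in 129.MOLF-Chr19 among 12671 compared. The higher genes were Slc35a5 at 1.54, the interferon-induced gene Ifi35 at 1.26, Tmem258 at 1.24, the transcription factor gene Sp3 at 1.23, Evl at 1.14, Kdm6b at 1.06 and the kinase gene Nek8 at 1.04. The lower genes were led by the kinetochore gene Dsn1 at −1.89, the Wnt receptor gene Fzd8 at −1.63, Plcxd2 at −1.59, Fam114a2 at −1.56, Rfng at −1.55, the cardiac troponin gene Tnni3 at −1.53, Cog1 at −1.49, Rasl10b at −1.40, the splicing factor gene Sf1 at −1.39 and the kinase gene Map3k12 at −1.35. Of the other expressed probe sets of the lower genes, 30 in 18 genes had a median of 0.05 and 2 passed 2-fold in the same direction. Those of the higher genes, 5 in 3 genes, had a median of 0.00 and none passed 2-fold, those of Kdm6b being at −0.46 and −0.04. With the mean of all probe sets of a gene, 1 gene was at least 2-fold higher and 11 lower. All the lower genes named here except Map3k12 were brightest on the 129/Sv embryo array. Dsn1 was at 2283 there, 581 in the 129.MOLF-Chr19 embryo and 753.5 to 868.6 in the testis. Fzd8 was at 2070, 628 and 678 to 816 in the same order. Such falls rest mainly on a high signal of that array, and a strain difference cannot be told from a feature of the array. The 129/Sv embryo array also held an 18S 3 prime control signal of 3053, against 571 to 787 on the other 5 arrays, and a hybridization control mean of 3044, against 1700 to 2222.

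The embryo's lists were led by immediate early and heat shock genes, with a median of 0.37 and the highest percentile, 100, and by cell cycle genes at 0.26 (99.9 percentile, 13 of 15 positive). The neural list lay at 0.25 (99.3 percentile). The liver list was at −0.20 (0.38 percentile), with none of 10 members positive, and the interferon response list of 3 compared genes at −0.36 (1.51 percentile). The peritubular and interstitial list lay at 0.29 (99.9 percentile), but at 0.05 (55.2 percentile) with the mean of all probe sets, where the meiosis list went from the 24.0 to the 1.44 percentile and the macrophage list from 5.30 to 2.49. The other 19 lists lay between the 2.62 and 86.6 percentiles.

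Across tissues, Tmem258 was at least 2-fold higher and Trim8 at least 2-fold lower in 129.MOLF-Chr19 in all 3 tissues, where 4.94e-06 and 2.78e-05 genes would be shared if the lists were independent. Both lie on chromosome 19 of GRCm38.p6. The lists are not independent, since strain differences correlated across genes between the E13.5 testis and the PN1 testis (r 0.302) or the embryo (r 0.336). Each tissue was also read with the same probe set, so a signal difference confined to 1 probe set would recur in all 3. The expected numbers are therefore no measure of evidence for a changed transcript. Kat2b, on chromosome 17, was also higher in the testis at both ages (1.13 and 1.30) and at 1.00, just short of 2-fold, in the embryo. Lipo3, on chromosome 19, was lower in the testis at both ages (−1.33 and −1.10), and at −0.38 in the embryo, with 129.MOLF-Chr19 at the floor. Map3k12 was lower in the PN1 testis (−1.28) and the embryo. The other expressed probe sets of Tmem258, Trim8 and Kat2b did not follow. In the E13.5 testis, the PN1 testis and the embryo, that of Tmem258 was at −0.08, 0.02 and −0.001. That of Kat2b was at 0.08, 0.46 and −0.78, the last opposite in sign to the probe set that represented the gene. Those of Trim8 averaged 0.29 and 0.02 over the tissues.

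Sf1, Pum3 and Cox15, the 3 chromosome 19 genes that the submitters name as lower in 129.MOLF-Chr19 in every tissue, differed by probe set. Sf1 had 1 probe set at −2.61 in the E13.5 testis, −2.62 in the PN1 testis and −3.09 in the embryo, 6.10-fold, 6.15-fold and 8.49-fold lower. 1 probe set of Pum3 was at −2.46, −2.48 and −2.25, and 1 of Cox15 at −1.68, −1.43 and −1.44, with 129.MOLF-Chr19 at the floor. The probe sets that represented these genes, chosen by their mean over all 6 arrays, were at −0.30, −0.40 and −1.39 for Sf1, at 0.20, 0.19 and 0.36 for Pum3, and at −0.25, −0.34 and −0.27 for Cox15, in the same order of tissues. In 129/Sv the lower probe set of Pum3 was brighter than the one that represented the gene (731 against 429 in the PN1 testis), as was that of Sf1 in the testis (5664 against 4008 at E13.5), so the choice of probe set was itself affected by the strain difference. The submitters chose these genes on the same arrays, so their direction here is not independent evidence. The submitters state 10, 266 and 35 changed genes for the E13.5 testis, the PN1 testis and the embryo, with 6, 13 and 5 on chromosome 19, against 11, 139 and 43 here, with 3, 6 and 4. No fold is stated for their PN1 count, so it need not rest on the same threshold.

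**Figure D3:**
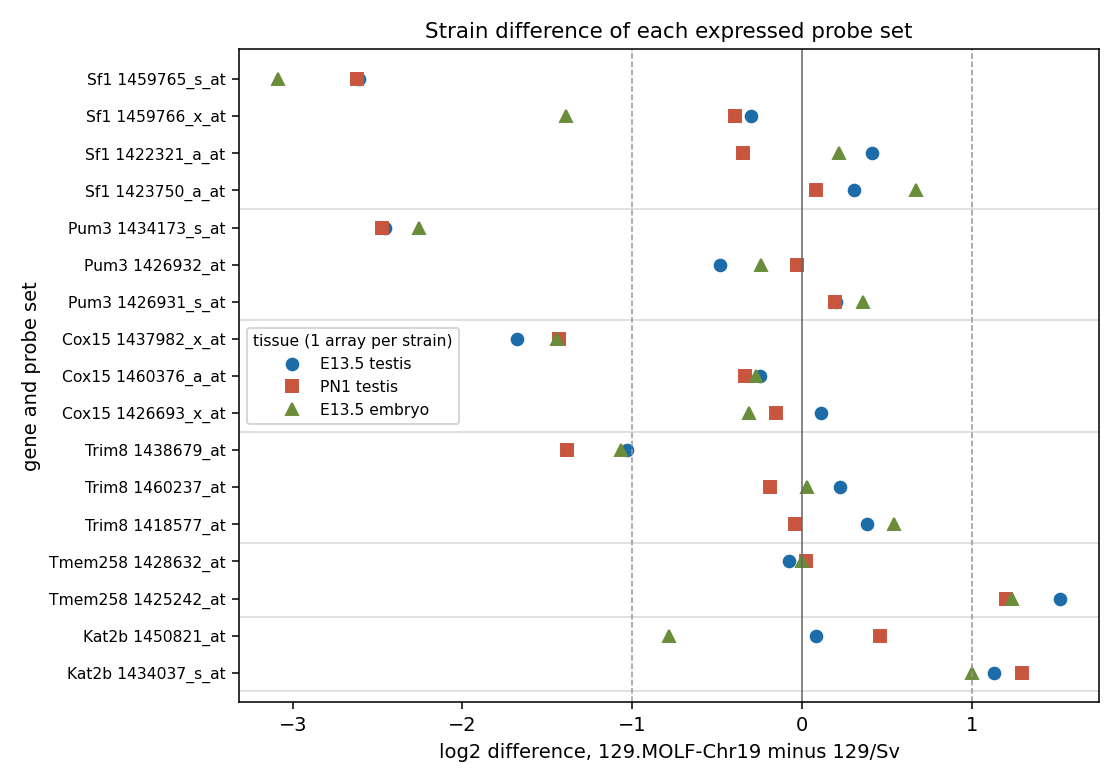
Log2 strain difference of each expressed probe set of 6 genes in the 3 tissues, 1 array per strain and tissue, with dashed lines at 2-fold. The topmost Sf1 probe set lies between −2.61 and −3.09 and the other Sf1 probe sets lie closer to 0.

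Fitted across the 3 tissues, 3 of 13027 genes differed between the strains. Tmem258 was higher by 1.32 (log2, SE 0.109, n = 3 arrays per strain), Kat2b was higher by 1.14 (SE 0.103) and Trim8 was at −1.16 (SE 0.109), each with a limma adjusted p of 0.0326 and in the same direction in 3 of 3 tissues. Sf1 at −0.70 (adjusted p 0.285), Pum3 at 0.25 (0.301) and Cox15 at −0.28 (0.285) did not pass. Fitted one probe set at a time, those 3 genes each had a probe set that did: Sf1 at −2.77 and Pum3 at −2.40 (limma adjusted p 0.00296 each) and Cox15 at −1.52 (0.0475), and no other probe set of 21373 passed. The cell cycle list rose as a set (camera adjusted p 0.0057; adjusted p = 0.956 with an estimated correlation), with 0 members past the threshold over all genes and 2 when adjusted over the list alone. The other 24 lists had camera adjusted p between 0.314 and 0.948. When adjusted over the list alone, the pluripotency list had 1 member higher and 1 lower, and the list of Sf1, Pum3 and Cox15, which the submitters chose on these arrays, had 1 higher and 2 lower. Test, median and mean differed in sign for the macrophage, Sertoli, Leydig, cholesterol, interferon, endothelial, cartilage and adrenal lists, none of them called. Without the E13.5 testis pair or the embryo pair, limma called 0 genes (694 and 1738 at an unadjusted p under 0.05), and without the PN1 pair 8 (Coro1c, Kat2b, Rpl27a, Sp3, Tmem109, Tmem258, Trim8 and Usp50). With no filter or with the mean of all probe sets it also called 0, with 2286 and 1484 at an unadjusted p under 0.05.

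Of the 3 called genes 2 lay on chromosome 19, 66.7% against 3.47% of the genes tested (Fisher's exact test, two-sided p 0.00352). These 2, Tmem258 and Trim8, were each called through 1 probe set that their other expressed probe sets did not follow. Fitted one probe set at a time, neither passed (limma adjusted p 0.0707 and 0.111). The share therefore need not reflect levels of whole transcripts. Within tissues, chromosome 19 held 3 of 11 changed genes in the E13.5 testis (27.3%), 6 of 139 in the PN1 testis (4.32%) and 4 of 43 in the embryo (9.30%), where proportional shares would give 0.386, 4.87 and 1.5. The median absolute difference of chromosome 19 genes lay at the 75.7, 99.1 and 75.2 percentiles of random lists in the same order, and their signed median (0.01, 0.02 and −0.02, against 0.07, 0.03 and 0.02 on other chromosomes) at the 0.06, 19.9 and 0.19 percentiles. Among genes at an unadjusted p under 0.05 across the 3 tissues, the odds ratio for lying on chromosome 19 was 2.10 for lower genes (Fisher's exact test, two-sided p 2.71e-05) and 1.19 for higher genes (p 0.244). On the values as deposited it was 1.53 for lower (p 0.00333) and 2.03 for higher genes (p 1.33e-04), and with quantile normalization 1.77 (p 3.00e-04) and 1.32 (p 0.104). The strain differences of chromosome 19 genes correlated across genes between the E13.5 and PN1 testis at r 0.506, and those of genes on other chromosomes at r 0.293. Genes are not independent replicates, and the difference between these values was not tested.

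In the testis alone, at 2 ages, limma called 0 of 12581 genes, with 1691 at an unadjusted p under 0.05. The 5 genes of smallest p were Kat2b at 1.22 (adjusted p 0.244), Tmem258 at 1.36 (0.244), Trim8 at −1.21 (0.326), Lipo3 at −1.21 (0.360) and Carnmt1 at −0.89 (0.369), none significant. All but Kat2b lie on chromosome 19. Sf1 was at −0.35, Pum3 at 0.20 and Cox15 at −0.29 (adjusted p 0.369, 0.433 and 0.369). The peritubular and interstitial list fell as a set (camera adjusted p 0.00693, median −0.16), and the cell cycle list (0.0324, median 0.20) and the erythroid list (0.0402, median 0.26) rose. No list passed with an estimated correlation (lowest adjusted p = 0.992), and no member of these 3 lists passed over all genes or when adjusted over the list alone. The other 22 lists had camera adjusted p between 0.246 and 0.990, and test, median and mean differed in sign for the muscle, Sertoli, neural, macrophage, Y-linked, ovarian and adrenal lists among them. On the values as deposited limma called 12 genes, with quantile normalization 5 (Carnmt1, Kat2b, Lipo3, Tmem258 and Trim8) and with no filter 370.

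From E13.5 to PN1, the embryonic globin genes Hbb-y, Hbb-bh1 and Hba-x and the pluripotency genes Dppa5a and Sox2 fell in the testis, and the Sertoli cell genes Inha and Fshr and the Leydig cell genes Hsd3b1 and Cyp11a1 rose. limma called 1959 of 13027 genes, 548 higher and 1411 lower at PN1 (n = 2 arrays per age). The largest rise among the 10 rising genes of smallest p was in Cst12, a cystatin, at the floor at E13.5 and at least 43.9-fold higher at PN1 (log2 5.46, SE 0.114). Pdlim3 rose by 3.70, the inhibin alpha gene Inha by 3.23 (SE 0.143), Spock2 by 2.71, 4930550L24Rik by 2.62, Myo7a by 2.50, the alpha-fetoprotein gene Afp by 2.48, which is a lower bound, Prss35 by 2.43, the germ cell gene Mael by 2.37 and Itih5 by 2.34. The embryonic globin genes Hbb-y at −5.60 (SE 0.114), Hbb-bh1 at −4.61 and Hba-x at −4.26 fell, as did Hmga2 at −4.87, the germ cell and pluripotency genes Dppa5a at −3.87 and Dppa3 at −3.59, Itga8 at −2.83, Sox11 at −2.77, Emx2 at −2.53 and Flrt2 at −2.44. Each of these 20 genes had a limma adjusted p of 5.85e-05 or less.

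Groups of genes moved by age as follows. The Leydig cell list rose (camera adjusted p 1.02e-04, adjusted p = 0.512 with an estimated correlation), with 6 of 8 tested members higher, among them the steroidogenic genes Hsd3b1 at 1.31 and Cyp11a1 at 1.39. The Sertoli cell list rose (0.00238, adjusted p = 0.648 with an estimated correlation), with 9 of 15 higher, such as Inha, Hsd17b3 at 1.63 and the FSH receptor gene Fshr at 1.27, and 3 lower, such as Rhox5 at −1.71. The cell cycle list fell (6.59e-06, adjusted p = 0.512 with an estimated correlation), with 9 of 15 lower and 11 when adjusted over the list alone, such as Bub1 at −1.13 and Top2a at −0.87. The pluripotency and embryonal carcinoma list fell (1.02e-04), with 6 of 15 lower and 8 when adjusted over the list alone, such as Sox2 at −2.14, and the erythroid list fell (1.90e-04), with 4 of 8 lower and 5 when adjusted over the list alone (adjusted p = 0.512 for both with an estimated correlation). The germ cell list rose (0.0241, adjusted p = 0.512 with an estimated correlation), with 7 of 20 higher and 3 lower, and 10 and 3 when adjusted over the list alone: Mael, the piRNA pathway gene Tdrd9 at 1.47 and Taf7l at 1.09 rose, and Dppa3 fell. The immediate early and heat shock list rose (8.53e-04, adjusted p = 0.512 with an estimated correlation), with 4 of 10 higher, such as Egr1 at 2.10 and Fos at 1.12, and 1 lower. The liver list rose (0.0133, adjusted p = 0.648 with an estimated correlation), but Afp was its 1 called member of 10. For the Leydig, Sertoli, immediate early and liver lists the counts adjusted over the list alone were equal to those over all genes.

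The peritubular and interstitial list, not called as a set (camera adjusted p 0.985), had 3 members higher and 3 lower, 4 and 5 when adjusted over the list alone: the smooth muscle genes Acta2 at 1.47 and Tagln at 1.78 rose, and Nr2f1 at −2.94 and Wnt5a at −1.35 fell. In the testicular germ cell tumor susceptibility list (0.363) Dmrt1 rose by 1.63 and Ccnd1 at −1.64, Kit at −0.94 and Atf7ip at −0.90 fell, also when adjusted over the list alone. Of the endothelial list (0.246) Kdr at −1.18 and Emcn at −1.14 fell, of the mesonephros list (0.401) Emx2 and Cdh16 at −1.02 fell and Ret at 0.64 rose, and of the ovarian somatic list (0.299) Wnt4 at −0.67 and Rspo1 at −0.73 fell. When adjusted over the list alone, each of these 3 lists also had 2 members lower, and the endothelial and mesonephros lists 1 higher. Pum3 was 1 of the 3 genes of the submitters' list (0.522) to fall, at −0.60. The camera adjusted p was 0.124 for the macrophage list, 0.188 for muscle, 0.222 for cholesterol synthesis, 0.246 for interferon response and for Y-linked genes and Xist, 0.299 for p53 targets, 0.667 for the neural list, 0.858 for cytochrome c oxidase, 0.944 for meiosis, and 0.985 for the adrenal and cartilage lists. For the peritubular and meiosis lists the test pointed up and the median was below 0 (−0.18 and −0.06), the latter above 0 with quantile normalization. Without the E13.5 testis array of 129/Sv the fit called 295 genes and without that of 129.MOLF-Chr19 296; of 63 called genes named by the rule, 27 lost their call without 1 of the arrays (21 and 25 without these 2), among them Bub1, Top2a, Fos, Kdr, Emcn, Kit, Atf7ip, Wnt4, Rspo1, Wnt5a, Cdh16, Ret and Pum3. With quantile normalization 787 genes were higher and 887 lower, and Pum3 and Wnt4 did not pass.

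The E13.5 testis differed from the E13.5 embryo, which shares its age, in 2933 of 13027 genes, 2237 higher and 696 lower in the testis (n = 2 arrays per tissue). The Sertoli cell genes Cst9 (at least 23.4-fold higher, the embryo at the floor), Aard at 4.14 (log2, SE 0.130) and Wt1 at 4.09, a gonadal transcription factor gene, were higher. So were the germ cell and pluripotency genes Dppa5a at 4.48 and Dppa3 at 3.85, Akr1cl at 4.22, the anti-Müllerian hormone receptor gene Amhr2 at 3.75, Defb19 at 3.73, Gucy1a1 at 3.56 and Rpl39l at 3.44, the last a lower bound. The liver genes Afp (at least 71.5-fold lower in the testis, at the floor there), Alb at −5.12 and Serpina6 at −4.22 were lower. The muscle genes Actc1 at −4.55 and Myl4 at −3.44, the neural genes Fabp7 at −4.36, Ncan at −3.79, Rtn1 at −3.71 and Stmn2 at −3.45, and the erythroid gene Hemgn at −3.29, a lower bound in size, were also lower. Each of these 20 genes had a limma adjusted p of 4.69e-06 or less.

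Of the fixed lists, the Sertoli cell list (camera adjusted p 4.98e-06) had 9 of 15 members higher in the testis and 1 lower, and the Leydig cell list (1.50e-05) had 7 of 8 higher, such as Cyp17a1 at 3.64, and Gramd1b lower at −0.77. Neither passed with an estimated correlation (adjusted p = 0.383 and 0.294). The germ cell list (4.75e-04, adjusted p = 0.294 with an estimated correlation) had 11 of 20 higher, such as Dazl, at least 36.9-fold, and Ddx4, at least 3.41-fold. The pluripotency and embryonal carcinoma list (1.63e-04, adjusted p = 0.383 with an estimated correlation) had 8 of 15 higher, such as Dppa4, at least 5.81-fold, and 1 lower, Sox2 at −0.45, chosen after its value was seen, as was Gramd1b. The liver list (5.95e-16) had 10 of 10 lower, the skeletal and cardiac muscle list (3.51e-13) 9 of 11, the neural list (2.14e-09) 7 of 10, the erythroid list (1.79e-08) 5 of 8 and the cartilage and bone list (0.0178) 2 of 4, with Col2a1 at −3.25. None of these 5 passed with an estimated correlation (adjusted p = 0.277 to 0.383). When adjusted over the list alone the counts were 10 higher and 1 lower for Sertoli cell, 10 and 1 for pluripotency, and 6 lower for erythroid, and were equal to those over all genes for the other 6 lists. Among lists not called as sets, the susceptibility list (0.0921) had Kitl at 1.57, Dmrt1, at least 2.90-fold, Atf7ip at 0.92, Dnd1 at 0.62 and Kit at 0.45 higher and Ccnd1 at −0.48 lower, Kit and Ccnd1 chosen after their values were seen. These counts were equal when adjusted over the list alone. The peritubular list (0.618) had 5 members higher, such as Tcf21 at 3.95, and 3 lower, and 6 and 3 when adjusted over the list alone. The other 14 lists had camera adjusted p between 0.0612 and 0.968, and test, median and mean differed in sign for the p53, cytochrome c oxidase, meiosis, mesonephros and submitters' lists among them. Without 1 array the count was 970 (testis of 129/Sv), 750 (testis of 129.MOLF-Chr19), 1588 (embryo of 129/Sv) or 1852 (embryo of 129.MOLF-Chr19), and 25 of 82 called genes named by the rule, Dnd1 and Col9a1 among them, lost their call without 1 of the arrays. With quantile normalization 1511 genes were higher and 1192 lower.

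**Figure D4:**
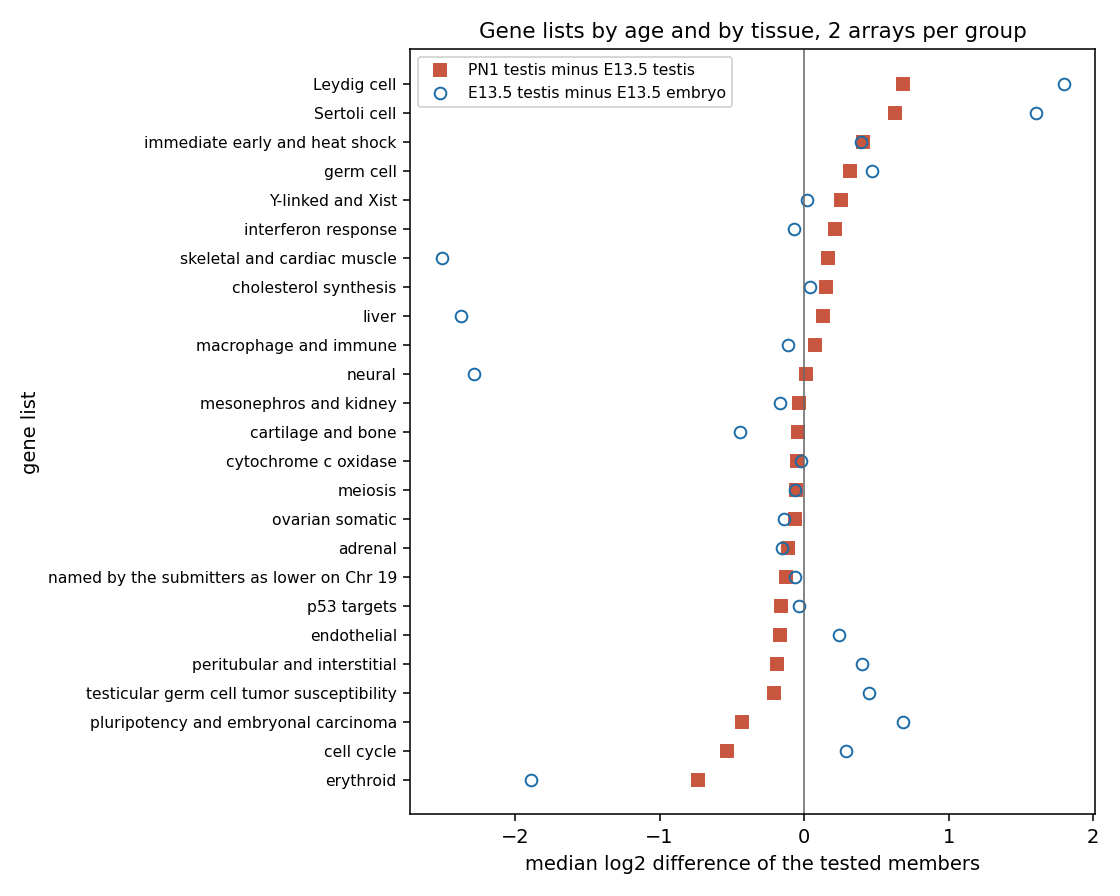
Median log2 difference of the tested members of each of the 25 fixed gene lists, for PN1 testis minus E13.5 testis and for E13.5 testis minus E13.5 embryo, 2 arrays per group. The Leydig cell list is at 0.68 and 1.80 and the erythroid list at −0.74 and −1.89; both comparisons use the E13.5 testis arrays, with opposite sign.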

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

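The tests of whole transcripts, sequence differences, RNA degradation, single probe sets, more germ cells and other splits of the arrays were chosen after the result was seen.

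Kdm6b differed between the strains in opposite directions, at −2.65 (log2) in the PN1 testis and 1.06 in the embryo, and the difference between the tissues was not tested. Its other 2 probe sets were at 0.03 and 0.27 in the PN1 testis and at −0.46 and −0.04 in the embryo. Among probe sets listed with no gene, which no comparison used, 3 in the E13.5 testis, 5 in the PN1 testis and 1 in the embryo were at least 2-fold higher in 129.MOLF-Chr19, and 3, 29 and 13 were lower.

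In Sf1, Pum3, Cox15 and Trim8, chromosome 19 genes, 1 probe set each was at least 2-fold lower in 129.MOLF-Chr19 in all 3 tissues. A fall of the whole transcript as large as that of the called probe set is argued against. The 9 other expressed probe sets of these genes had a median difference of 0.022, and the interval of each of the 9 excluded the change of the called probe set. The called probe sets were picked for being lower, and a smaller fall is not excluded. 1 other probe set of Sf1 was at −0.70 (−1.2 to −0.187) and 1 of Cox15 at −0.28 (−0.512 to −0.0557). In the other direction, 1 of Sf1 was at 0.35 (0.0291 to 0.679) and 1 of Pum3 at 0.25 (0.0136 to 0.49). Sequence differences of the MOLF chromosome under the probes remain a candidate explanation: among probe sets past an unadjusted p of 0.05 and 1.5-fold, those on chromosome 19 were lower more often than others, with an odds ratio of 2.968 (Fisher's exact test, p 0.069), but of 1.03 on the values as deposited and 1.70 with quantile normalization. Probe sequences and MOLF variants were not among the data at hand, which keeps this open. Genes at an unadjusted p under 0.05 lay on chromosome 19 with odds ratios of 2.10 (lower) and 1.19 (higher). On the values as deposited these were 1.53 and 2.03. With each probe set on its own and arrays centred, lower probe sets had an odds ratio of 2.79 (Fisher's exact test, two-sided p 1.44e-11). Higher probe sets had 1.12 (Fisher's exact test, two-sided p 0.359). Probe sets of a gene are not independent replicates for this test. A change of splicing or of transcript ends in this strain was not tested and is also open.

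The 113 lower genes of the PN1 testis rest largely on single probe sets. In the 85 genes with other expressed probe sets, a lower level of the whole transcript is argued against for the genes as a set. Those 177 probe sets had a median of −0.045 (95% bootstrap interval −0.11 to 0.022). The intervals for the PN1 testis in this section reflect the spread between genes or probe sets on 1 array per strain. They do not measure variation between pools or arrays. A lower level of the whole transcript is not argued against for each gene, since 24 of the 177 passed 2-fold in the same direction. The other probe sets of Sdc4 (−1.01) and Rian (−1.19) were lower, and those of Ccnd2 lay between −0.32 and −2.40. Rian and Ccnd2 were chosen after their values were seen. A general loss of signal from bright probe sets on this array is argued against, because the brightest 10% of expressed probe sets other than the called ones had a median of −0.021 (−0.033 to −0.01, n = 1996). The called probe sets were left out, so this median cannot show a loss confined to some bright probe sets. RNA degradation in this pool stays open: the 3 prime to 5 prime ratio over 129/Sv was 1.55 for Actb and 1.20 for Pcx but 1.02 for Gapdh and 0.862 for Tfrc, a geometric mean of 1.133, and the middle Actb probe set, at 1517 against 12440, fell by more than the 5 prime one, at 2778 against 12810, which is no graded loss toward the 5 prime end. A local defect of the array could not be examined without probe positions, and a strain difference in transcript isoforms was not tested.

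The 26 higher genes of the PN1 testis include Cer1, Pou5f1 and Otx2, at intensities of 1076, 454 and 401 in 129.MOLF-Chr19. Single probe sets are argued against for the 11 genes with other expressed probe sets as a set, whose median was 1.113 (0.585 to 1.81), but not for Amot (0.27 and −0.07), Tmem258 (0.02) and Kat2b (0.46), or the other 15 genes. More germ cells in the pool are argued against, since the germ cell list had a median of 0.0019 (−0.047 to 0.082, n = 20 genes). With 1 array per strain, this interval reflects the spread between genes and not that between pools. Embryonal carcinoma cells in the pool, which the series text reports in PN1 testes of this strain, may be a source of these transcripts, but a second list of 27 epiblast, embryonal carcinoma and epithelial genes, fixed before its values were looked at, had a median of 0.14 over 20 compared genes, at percentile 93.83, short of the 95th that the test required. With the mean of all probe sets the list lay at 99.8, and 15 of 20 members were positive. It was scored on the same PN1 arrays that gave the 26 higher genes, so it is no independent evidence. A difference in the composition of pools of 12 and 25 testis pairs stays open.

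The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The strain split called 3 genes and the highest of the others 101, and 3 splits called 3 or more. The 3 others that part every tissue pair, as the strain split does, called 0 genes each by limma (532, 516 and 162 at an unadjusted p under 0.05, against 2056). Any offset that the 3 pairs share enters the spread of those splits, so these counts cannot tell a strain difference from an effect of scaling. The direction of the unadjusted hits on other chromosomes did follow the scaling. With arrays centred 1333 were higher and 615 lower, and on the values as deposited 558 and 1267. The splits with 101 calls keep 2 tissue pairs whole and rest on the difference between the PN1 arrays alone, which points to a structure of the samples, the PN1 pair differing in many genes.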

How the results depend on the processing

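The alternatives that asked all expressed probe sets of a gene to pass, that left out genes with 1 expressed probe set and that took list medians from the mean of all probe sets were chosen after seeing the data. Of the counts and values that answer a comparison, 74 of 115 alternatives stayed within 1.5 times or kept their call and 41 moved. Values near 0 did change sign: 34 of 175 list medians did so on the values as deposited or with quantile normalization, none of them above 0.159 in size, as did the PN1 pluripotency list with the mean of all probe sets (−0.01 to 0.14). Pum3, uncalled, went from 0.20 to −0.91 in the E13.5 testis with that mean. The E13.5 testis count of 11 became 6 with quantile normalization, 5 with the mean of all probe sets, 31 with each probe set on its own, 313 at 1.5-fold, 1 at 3-fold and 0 among genes with 2 or more expressed probe sets that all had to pass. The PN1 testis count of 139 became 57 with the mean, 410 with each probe set, 502 at 1.5-fold, 39 at 3-fold, 96 without genes that have 1 expressed probe set and 8 among the remaining genes where all had to pass. The embryo count of 43 became 12 with the mean, 69 with each probe set, 423 at 1.5-fold, 3 at 3-fold and 0 where all of 2 or more had to pass. These last counts leave out genes with 1 expressed probe set, of which 3, 17 and 4 were at least 2-fold higher and 4, 28 and 18 lower in the 3 tissues, so the moves rest on both choices. The 2 genes shared by all tissues became 0 with the mean, 5 with each probe set and 0 at 3-fold. Across 3 tissues the 3 limma calls became 0 without the tissue block (283 at an unadjusted p under 0.05), 0 with no filter, 0 with the mean, and 0 to 8 leaving out each pair. Across the testis the 0 limma calls (1691 at an unadjusted p under 0.05) became 12 on the values as deposited, 5 with quantile normalization and 370 with no filter. The count by age ranged from 295 to 2189 and that by tissue from 750 to 1852 leaving out each array, where the lone array was assumed to vary like the other groups. The chromosome 19 share of 66.7% was 27.3%, 4.32% and 9.30% among the 2-fold genes of the 3 tissues, and had no value where no gene was called, with no filter and with the mean. With an estimated correlation the called lists went from 1, 3, 8 and 9 to 0, 0, 0 and 0. The thresholds, the number of genes tested and the preset correlation account for some of these by construction; otherwise the cause was not tested. Of single named genes in the fits, 57 values lost their call and 1457 kept it or stayed uncalled under other settings, and 125 lost it and 473 did not leaving out an array or pair. No paired analysis was possible because each array held a separate pool of several animals and the labels tie no pool of 1 strain to a pool of the other. Tissue or strain entered as a block instead, which sets the strains against each other within each tissue but matches no animals. Genes near the array floor have differences that are compressed or only bounded.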

Other observations

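The values of the lower PN1 genes in the other tissues and those of single list members were chosen after the result was seen.

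The 113 genes lower in the PN1 testis of 129.MOLF-Chr19 did not share their direction in the embryo. Their median strain difference was −0.10 in the E13.5 testis, where 41 of 113 were positive against 59.2% of all genes, and 0.24 in the embryo, where 87 of 113 were positive against 53.2% of all genes. Correlated across genes, the strain differences of the PN1 testis and the embryo had an r of 0.0402, those of the E13.5 and PN1 testis 0.302, and those of the E13.5 testis and embryo 0.336.

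In the second list of epiblast, embryonal carcinoma and epithelial genes, Dsp was at 0.84 and Pim2 at 0.81 in the PN1 testis. In the pluripotency list, Lefty1 at 0.75, Sall4 at 0.58 and Dppa4 at 0.54 followed Pou5f1, but 6 of the 12 members were positive, and Lin28a at −0.45 and Tcl1 at −0.31 went the other way. The genes were chosen after their values were seen.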
